A study of Homo sapiens with 18 samples.

How the data were processed

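Poly(A)-selected RNA from NCI-H211 cells that carried Cas9 was sequenced after infection with sgPOU2F3 or sgRosa in 3 stable lines (empty vector, WT cDNA and L191A cDNA). RNA was isolated with TRIzol and libraries were made with a TruSeq kit, per the labels' protocols. The labels put 3 libraries in each of 6 groups, and columns were matched to samples by name. The deposited values were TPM, made by the authors with kallisto and the hg38 build, per the submitters' processing notes. The version of kallisto, the transcript set and any strand setting are not given in the sources used here. Every column had the same total, so library depth was lost and no counting error could be given.

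The table held 19875 entries, of which 131 were left out because they named no gene: 104 were fragments of gene descriptions and 27 were symbols turned into spreadsheet dates. They held 1.64% to 2.43% of the TPM of a library. Of the entries, 97.1% had a name found in the gene name tables. Coordinates and transcript lengths came from GENCODE annotation of GRCh38, the same assembly as hg38, and 98.0% of the genes tested had a length.

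Values were taken as log2(TPM + 1), a scale that understates the change of genes at low TPM. Genes with a mean of at least 1 TPM over the 18 libraries were tested, 13066 in all. limma 3.58.1 (R 4.3.3) fitted 1 coefficient per group to all 18 libraries with an intensity trend of the variance, and 12 contrasts were tested two-sided with Benjamini-Hochberg adjustment within each, at an adjusted p of 0.05. They were sgPOU2F3 minus sgRosa in each line, the pairs of lines under each guide, and the 3 differences of the sgPOU2F3 effect between lines. All groups share 1 estimate of the spread, since a pair of groups alone leaves few degrees of freedom. The tests, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined.

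Genes were named by rule. The octamer family was always named (POU2F3, POU2F1, POU2F2, POU2AF1, POU2AF2 and POU2AF3). The 10 largest rises and falls were named for the 3 sgPOU2F3 effects and for L191A against WT under sgPOU2F3, and the 5 largest each way for the other contrasts. A named gene had to pass the test, reach a mean of 5 TPM in the higher group and, except in interactions, have no overlap between replicates, and clone-type or unnamed loci were passed over. Up to 4 members with the smallest p were named per list described for the sgPOU2F3 effects, and none, for length, in the other contrasts. Other genes shown by level were taken from these.

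Of 34 gene lists, 30 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. The lists were tuft markers, tuft transcription factors and coactivators, taste-type signalling, eicosanoid synthesis, the octamer factor family, neuroendocrine, YAP and TAZ targets, mesenchymal, epithelial, basal and squamous, secretory airway and gut, ciliated airway, alveolar, lymphoid and myeloid, erythroid and megakaryocyte, endothelial, the embryonic kidney packaging line, S phase, G2 and M phase, MYC and ribosome biogenesis, cytosolic ribosomal proteins, p53 targets, interferon response, MHC and antigen presentation, NF-kB and inflammatory, apoptosis regulators, integrated stress response, cholesterol synthesis, hypoxia and glycolysis, Wnt targets, Notch pathway, ERK feedback and growth factor receptors, replication-dependent histones, and housekeeping controls. POU2F3 was left out of every list except the octamer family, which was read gene by gene. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Response sets were the genes called at 2-fold or more in empty-vector cells, read in WT and L191A libraries. Reading them less the median of all genes was added after the data were seen.

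Alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, the replicate number as a block, no variance trend, a robust variance prior (genes only, as the list tests have no such option), fits of only the groups compared, other set sizes (1.5-fold and 4-fold) and each library of the groups compared left out in turn. Added after seeing the data were the removal of 1 or both skewed libraries, array weights, removal of each library's lowess trend (span 0.3) against log2 transcript length, and response sets taken again within each setting. The joint (REML) estimate of array weights did not converge, so the gene-by-gene estimate was used. The fit was tested on simulated data with known changes among 13066 genes. For sgPOU2F3 in empty-vector cells, 44.0% of 200 genes changed 2-fold and 94.0% of those changed 4-fold were called, with 2 and 11 false calls. In L191A cells these were 44.0% and 97.0%, with 6 and 10 false calls. For the difference between L191A and WT cells they were 0.0% and 69.5%, with 0 and 5. The rates need not hold for the real libraries, 2 of which were skewed. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.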

Results

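RNA-seq was carried out on NCI-H211, an established small cell lung cancer line of the POU2F3-positive, tuft-cell-like subtype, in cells that carried Cas9. POU2F3 is an octamer-binding transcription factor that specifies tuft cells, which are chemosensory epithelial cells with taste-type signalling. Stable lines carried an empty vector, a guide-resistant wild-type POU2F3 cDNA (WT), or that cDNA with the L191A change, a leucine-to-alanine substitution (L191A). Each line was infected in triplicate with lentivirus carrying a guide against POU2F3 (sgPOU2F3) or a control guide (sgRosa), and RNA was taken on day 5. This gave 6 groups of 3 libraries, 18 in all. Read depth was unknown, so no interval or detection limit was set from counts. The median over the 13066 genes tested was 7.05 to 26.43 TPM per library. Replicates were separate infections of 1 stable line each, so p-values did not measure the spread between independently made lines. The shared spread included that of a skewed pair of libraries, described next.

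A pair of libraries stood apart from the rest. In L191A sgRosa replicate 1 the median gene was at 7.05 TPM, against 19.19 TPM in each of the other replicates of its group. The 100 highest genes took 47.71% of its TPM and cytosolic ribosomal protein genes 37.96%. WT sgPOU2F3 replicate 1 was intermediate, with a median of 12.73 TPM, 43.45% in the 100 highest genes and 32.76% in ribosomal protein genes. The other 16 libraries had 15.74% to 26.4% of TPM in ribosomal protein genes. In both, long transcripts were low relative to the other replicates, with a slope of −0.365 and −0.135 log2 units per doubling of transcript length. Counts are therefore also given in the 16 libraries without these, a choice made after the data were seen, as are list medians and p-values where they moved by over 1.5 times or changed a call.

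**Figure D1:**
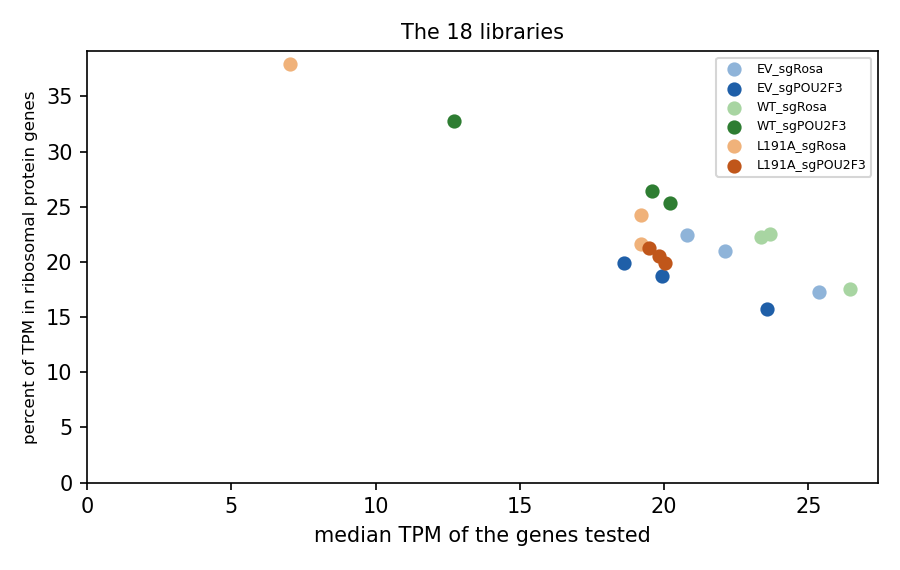
Each point is 1 of the 18 libraries, by group, with the median TPM of the genes tested on the x axis and the percent of TPM in cytosolic ribosomal protein genes on the y axis. L191A sgRosa replicate 1 lies at 7.05 TPM and 37.96%, and WT sgPOU2F3 replicate 1 at 12.73 TPM and 32.76%.

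The targeted gene was read first. POU2F3 (chromosome 11, 120236640 to 120319944, plus strand, protein-coding, GRCh38) was at 729 ± 108 TPM (SD, n = 3) in empty-vector sgRosa cells and at 281 ± 33.1 TPM in empty-vector sgPOU2F3 cells. The sgRosa libraries read 681.7, 653.7 and 853 TPM and the sgPOU2F3 libraries 252.6, 317.6 and 274.2 TPM, without overlap. The log2 change of −1.37 (SE 0.48) missed the threshold in limma (adjusted p = 0.0617). The spread, shared by all groups, took in an L191A sgRosa library at 142 TPM. WT cells held 1792 ± 90 TPM with sgRosa (1701, 1881 and 1796 TPM) and 1154 ± 114 TPM with sgPOU2F3 (1136, 1276 and 1049 TPM). L191A cells held 646 ± 25.7 TPM with sgPOU2F3 (620.9, 672.2 and 645.2 TPM). Their sgRosa libraries read 142 (skewed replicate 1), 1053 and 831 TPM. The log2 change in L191A cells was 0.37 (adjusted p = 0.589) with all libraries and −0.53 (adjusted p = 0.0154) without the 2 skewed ones, both by limma. Reads of the cDNA may be counted as POU2F3, and a Cas9 break need not lower the mRNA, so this level did not measure how much endogenous protein was lost.

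The other octamer-family genes were read gene by gene. C11orf53, the gene of the POU2F3 coactivator POU2AF2 (chromosome 11, 111245805 to 111286401, plus strand), fell in empty-vector cells from 601 ± 19.4 to 282 ± 2.04 TPM (SD, n = 3), a log2 change of −1.09 (SE 0.15, limma adjusted p = 9.43e-05). It fell in L191A cells too (−0.98, SE 0.15, adjusted p = 0.000521). In WT cells its log2 change was −0.38 (adjusted p = 0.0883), and the difference of the response from that of empty-vector cells was 0.70 (adjusted p = 0.0584). COLCA2, the gene of the related coactivator POU2AF3 (chromosome 11, 111298555 to 111308735, plus strand), lies beside it and fell in empty-vector cells from 13.2 ± 0.427 to 6.68 ± 1.09 TPM (−0.90, SE 0.28, adjusted p = 0.0381). POU2F1, a broadly expressed octamer factor (chromosome 1, 167220829 to 167427345, plus strand), stood at 8.23 ± 0.975 to 6.12 ± 1.49 TPM there (log2 change −0.39, adjusted p = 0.519). POU2F2 and POU2AF1, a lymphoid octamer factor and its coactivator, did not reach the mean of 1 TPM needed for the test. Their group means were 0.149 to 0.998 TPM and 0.445 to 1.36 TPM. Further calls of limma in this family follow (adjusted p in brackets). Under sgRosa, L191A cells lay below WT and below empty-vector cells for POU2F1 (−0.98 [0.0311] and −0.99 [0.0424]), COLCA2 (−1.03 [0.00844] and −1.04 [0.014]) and C11orf53 (−0.94 [0.000273] and −0.84 [0.00134]). The POU2F1 and COLCA2 differences from WT were −0.42 and −0.67 without the skewed libraries, and that of POU2F1 turned to 0.27 with the length trend removed. Under sgPOU2F3, C11orf53 was 0.80 [0.00135] in WT and −0.73 [0.00807] in L191A relative to empty-vector cells and −1.53 [3.48e-06] in L191A relative to WT cells, and POU2F3 was 2.03 [0.00677] in WT relative to empty-vector cells.

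**Figure D2:**
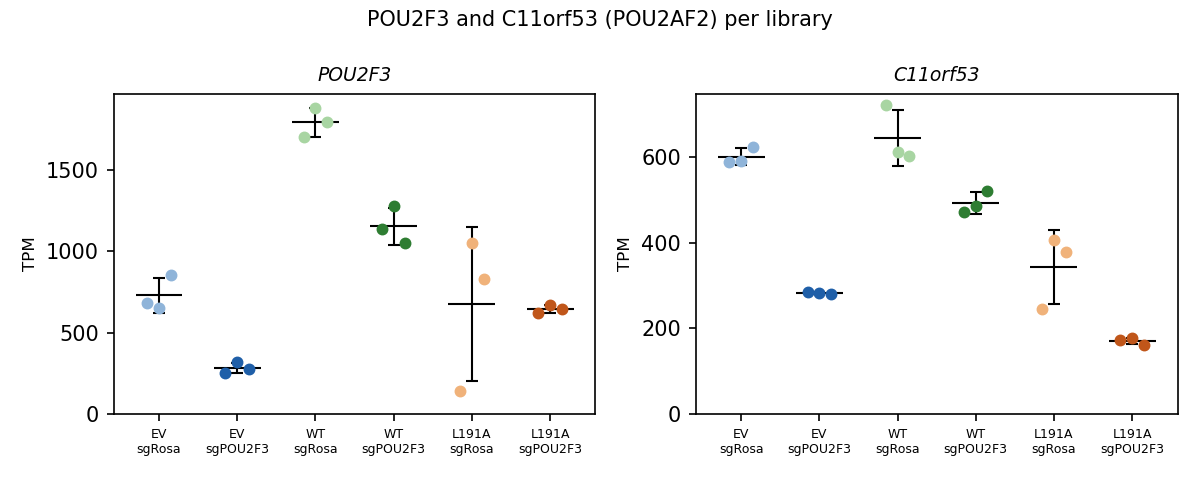
TPM (y axis, linear) of POU2F3 and of C11orf53, the gene of POU2AF2, in each library of the 6 groups, where points are libraries, lines the mean and bars the SD of n = 3. In empty-vector cells POU2F3 was at 729 TPM with sgRosa and 281 TPM with sgPOU2F3, and 1 L191A sgRosa library lay at 142 TPM.

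The first comparison asked what targeting endogenous POU2F3 does where no cDNA covers its loss. In empty-vector cells camera called the YAP and TAZ list higher and the tuft and taste-type lists lower, none of which held with an estimated correlation. KRT17, a basal keratin, went from 2.34 ± 0.58 to 506 ± 22.3 TPM (SD, n = 3), and CYR61, a matricellular protein and YAP target, from 2.3 ± 0.232 to 444 ± 41.2 TPM. GNG13, a G protein subunit of taste cells, went from 318 ± 46.5 to 60.3 ± 2.51 TPM. The 10 largest rises, as log2 change ± SE, were KRT17 (7.26 ± 0.21), CYR61 (7.08 ± 0.25), FOSL1 (an AP-1 subunit, 5.94 ± 0.32), THBS1 (thrombospondin, 5.67 ± 0.46), PLAU (urokinase, 5.51 ± 0.22), AMOTL2 (an angiomotin of the Hippo pathway, 5.51 ± 0.40), IGFBP4 (5.48 ± 0.28), SERPINB7 (5.38 ± 0.22), TGFB2 (5.36 ± 0.32), LIF (a cytokine, 5.24 ± 0.39). The largest adjusted p among them was 2.45e-07 (limma). The 10 largest falls were TAS2R60 (a bitter taste receptor, −3.74 ± 0.41), PRR15L (−2.88 ± 0.18), SH2D6 (a tuft marker, −2.74 ± 0.30), KLHDC7A (−2.64 ± 0.37), CLPSL2 (−2.58 ± 0.28), RGS21 (a regulator of G protein signalling, −2.57 ± 0.29), RGL1 (−2.55 ± 0.37), BIK (pro-apoptotic, −2.51 ± 0.19), CHAD (−2.50 ± 0.25), TAS2R38 (a bitter taste receptor, −2.44 ± 0.79). The largest adjusted p among these was 0.045.

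Of 39 tuft markers, 1 rose and 18 fell (2 and 23 adjusted over the list alone, 2 and 31 in 16 libraries), with a median of −0.80 (camera adjusted p = 5.3e-09, and 0.473 with an estimated correlation). ANXA13 (−1.90), RGS13 (−2.32), GNG13 (−2.37) and SH2D6 (−2.74) had the smallest p. Of 14 taste-type signalling genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone, 1 and 11 in 16 libraries), with a median of −1.59 (camera adjusted p = 2.56e-06, and 0.371 with an estimated correlation). RGS13 (−2.32), GNG13 (−2.37), RGS21 (−2.57) and CALHM3 (−0.99) had the smallest p. Of 8 genes of eicosanoid synthesis, 0 rose and 4 fell (0 and 4 adjusted over the list alone, 0 and 5 in 16 libraries), with a median of −0.50 (camera adjusted p = 0.0197, but 0.074 in 16 libraries, and 0.4 with an estimated correlation). PTGS2 (−1.90), PLA2G4A (−1.26), LTA4H (−0.53) and HPGD (−0.80) had the smallest p. Of 8 tuft transcription factors and coactivators, 1 rose and 4 fell (1 and 4 adjusted over the list alone, 1 and 7 in 16 libraries), with a median of −0.80 (camera adjusted p = 0.046, and 0.588 with an estimated correlation). C11orf53 (−1.09), SPIB (0.90), MYB (−0.95) and COLCA2 (−0.90) had the smallest p. Several taste-type and eicosanoid genes also belong to the tuft markers, so these lists are not independent.

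The list of YAP and TAZ targets, the transcriptional output of the Hippo pathway, was called higher, as were the mesenchymal, epithelial and basal lists, none of which held with an estimated correlation. Of 24 YAP and TAZ targets, 17 rose and 1 fell (17 and 1 adjusted over the list alone, 18 and 2 in 16 libraries), with a median of 2.72 (camera adjusted p = 9.51e-21, and 0.155 with an estimated correlation). CYR61 (7.08), ANKRD1 (4.80), IGFBP3 (4.64) and GADD45B (3.27) had the smallest p. Of 18 mesenchymal genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, 10 and 2 in 16 libraries), with a median of 1.21 (camera adjusted p = 2.35e-08, and 0.155 with an estimated correlation). TGFBI (5.00), LUM (2.97), VIM (3.61) and SNAI2 (3.70) had the smallest p. Of 26 epithelial genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 10 and 7 in 16 libraries), with a median of 0.21 (camera adjusted p = 0.00612, and 0.588 with an estimated correlation). KRT19 (1.49), KRT18 (1.28), KRT8 (1.80) and KRT7 (1.64) had the smallest p. Of 9 basal and squamous genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, 4 and 1 in 16 libraries), with a median of 0.32 (camera adjusted p = 0.000166, and 0.176 with an estimated correlation). KRT17 (7.26), KRT16 (4.15) and S100A2 (3.08) had the smallest p. KRT16 and KRT17 have near-identical pseudogene copies and KRT8 and KRT18 share pseudogene sequence, so the division of reads among copies is uncertain.

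Camera called the inflammatory and antigen presentation lists higher as well, and with an estimated correlation too. The chemokine CXCL8 went from 1.02 ± 0.369 to 32.6 ± 1.13 TPM (SD, n = 3) and the cytokine IL6 from 0.227 ± 0.0535 to 21.3 ± 0.54 TPM. Of 22 NF-kB and inflammatory genes, 20 rose and 0 fell (22 and 0 adjusted over the list alone, 22 and 0 in 16 libraries), with a median of 1.72 (camera adjusted p = 3.19e-25, and 0.0124 with an estimated correlation). CXCL8 (4.07), IL6 (4.19), ICAM1 (3.65) and IER3 (2.15) had the smallest p. Of 16 genes of MHC and antigen presentation, 10 rose and 0 fell (12 and 1 adjusted over the list alone, 12 and 1 in 16 libraries), with a median of 0.95 (camera adjusted p = 1.68e-09, and 0.00169 with an estimated correlation). HLA-C (1.61), B2M (0.88) and PSMB9 (2.32) were among those with the smallest p. HLA-C has close paralogs, so its reads may be divided among them. Of 29 MYC and ribosome biogenesis genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone, 28 and 0 in 16 libraries), with a median of 0.65 (camera adjusted p = 6.58e-12, and 0.155 with an estimated correlation). PES1 (0.86), NOP16 (1.14), RRP9 (1.24) and MRTO4 (0.89) had the smallest p. Of 27 genes of ERK feedback and growth factor receptors, 10 rose and 2 fell (12 and 2 adjusted over the list alone, 16 and 3 in 16 libraries), with a median of 0.57 (camera adjusted p = 1.14e-06, and 0.533 with an estimated correlation). FOSL1 (5.94), IER3 (2.15), DUSP5 (2.91) and ETV4 (1.95) had the smallest p.

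Camera called further lists in empty-vector cells, none of which held with an estimated correlation. Of 42 S phase genes, 6 rose and 0 fell (3 and 0 adjusted over the list alone, 17 and 2 in 16 libraries), with a median of 0.17 (camera adjusted p = 0.00385, and 0.588 with an estimated correlation). TIPIN (0.59) and FEN1 (0.42) had the smallest p. Of 9 ciliated airway genes, 0 rose and 2 fell (0 and 5 adjusted over the list alone, 0 and 6 in 16 libraries), with a median of −0.82 (camera adjusted p = 0.0218, but 0.0572 in 16 libraries, and 0.403 with an estimated correlation). TPPP3 (−1.05) and RSPH1 (−1.38) had the smallest p. Of 24 genes of the integrated stress response, 1 rose and 8 fell (1 and 9 adjusted over the list alone, 3 and 13 in 16 libraries), with a median of −0.40 (camera adjusted p = 0.0166, but 0.0694 in 16 libraries, and 0.596 with an estimated correlation). PCK2 (−1.14) and PHGDH (−1.22) had the smallest p. Of 21 replication-dependent histone genes, 0 rose and 7 fell (0 and 9 adjusted over the list alone, 0 and 10 in 16 libraries), with a median of −0.57 (camera adjusted p = 0.0122, but 0.0832 in 16 libraries, and 0.155 with an estimated correlation). HIST1H2BD (−1.09) and HIST2H2BE (−1.27) had the smallest p. Of 26 housekeeping controls, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 9 and 2 in 16 libraries), with a median of 0.07 (camera adjusted p = 0.0122, and 0.371 with an estimated correlation). B2M (0.88) and PSMB2 (0.86) had the smallest p. Histone genes are near-identical and largely lack poly(A) tails, so their values are uncertain.

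The lists that camera did not call are given as genes that rose and fell, the same adjusted over the list alone and in 16 libraries, the median and camera's adjusted p. For cell types these were 1 and 3 of 12 neuroendocrine genes (1 and 5, 2 and 6, median −0.40, adjusted p = 0.178), 0 and 4 of 7 lymphoid and myeloid genes (0 and 4, 1 and 4, median −0.47, adjusted p = 0.317), 1 and 0 of 7 alveolar genes (1 and 0, 2 and 0, median −0.18, adjusted p = 0.226) and 1 and 1 of 10 genes of the embryonic kidney line used to package virus (1 and 1, 1 and 2, median −0.16, adjusted p = 0.818). For cell state they were 5 and 1 of 20 interferon response genes (5 and 1, 6 and 5, median 0.02, adjusted p = 0.0601), 6 and 2 of 26 p53 targets (7 and 3, 7 and 8, median −0.11, adjusted p = 0.226), 3 and 3 of 22 apoptosis regulators (5 and 4, 8 and 9, median 0.01, adjusted p = 0.648), 0 and 4 of 79 cytosolic ribosomal protein genes (0 and 1, 2 and 25, median −0.16, adjusted p = 0.117) and 0 and 3 of 54 G2 and M phase genes (0 and 2, 7 and 24, median −0.15, adjusted p = 0.71). For metabolism and signalling they were 1 and 1 of 23 cholesterol synthesis genes (1 and 1, 4 and 10, median −0.19, adjusted p = 0.653), 1 and 4 of 28 hypoxia and glycolysis genes (4 and 5, 10 and 9, median −0.15, adjusted p = 0.707), 0 and 1 of 15 Wnt targets (0 and 0, 4 and 5, median −0.07, adjusted p = 0.85) and 3 and 1 of 17 Notch pathway genes (3 and 1, 5 and 3, median 0.08, adjusted p = 0.163). Against other genes, camera placed the alveolar, p53, hypoxia and Wnt lists higher although their medians were below 0. The secretory airway and gut, erythroid and megakaryocyte, and endothelial lists had 3, 2 and 3 measured members and were not tested. In all, 2280 of 13066 genes changed, 1038 higher and 1242 lower, with a median of −0.13 over all genes. Of these, 445 rose and 498 fell by at least 2-fold. Without the skewed libraries, neither in this comparison, 6758 were called (2489 higher and 4269 lower, 2280 shared).

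**Figure D3:**
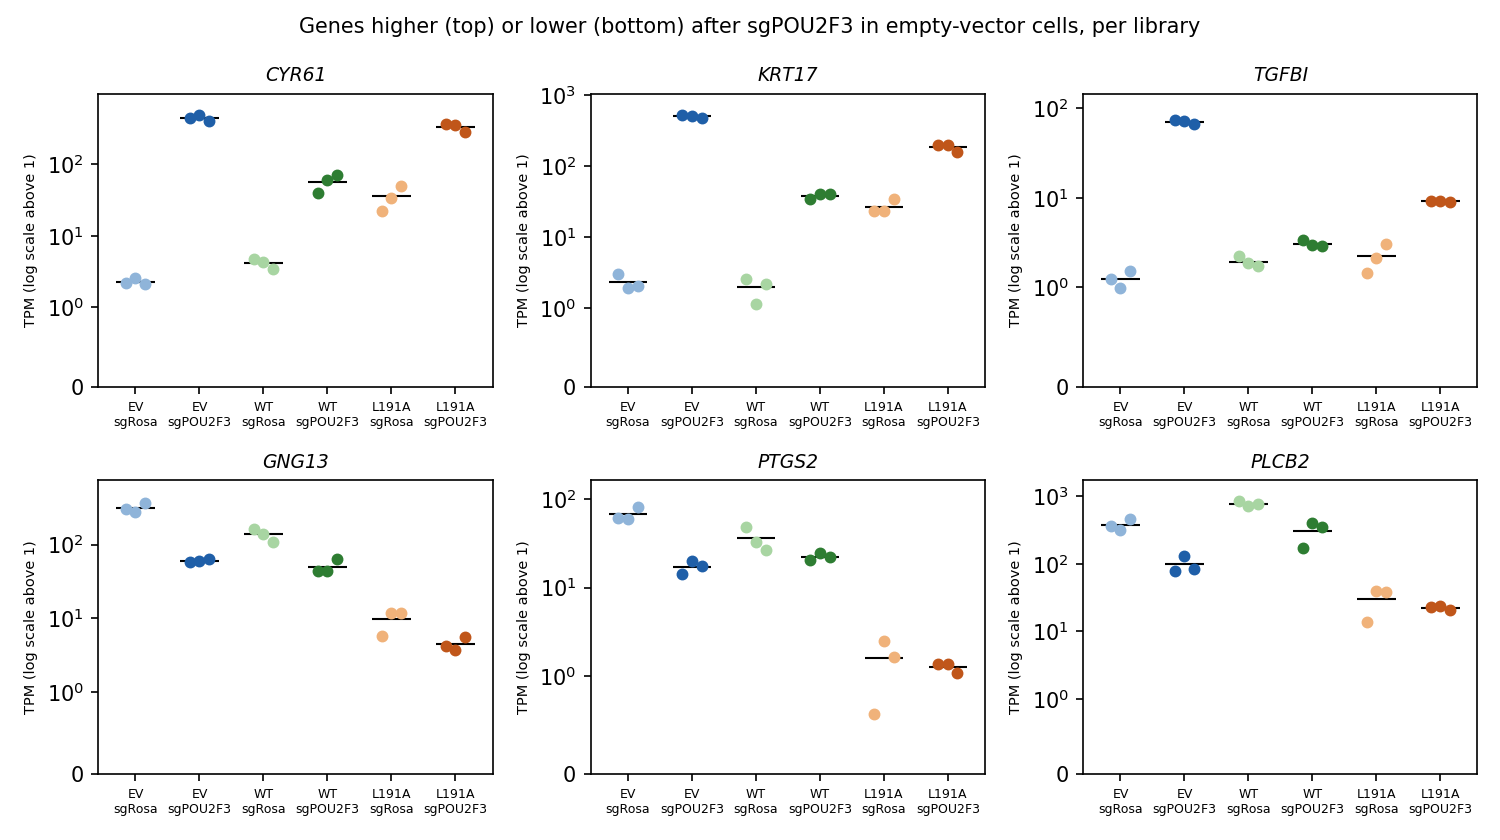
TPM (y axis, linear below 1 TPM and log scale above) of CYR61, KRT17 and TGFBI (top) and GNG13, PTGS2 and PLCB2 (bottom) in each library of the 6 groups, where points are libraries and lines the group means. The mean of CYR61 went from 2.3 to 444 TPM in empty-vector cells, from 4.17 to 56.9 TPM in WT cells and from 35.4 to 335 TPM in L191A cells.

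The second comparison asked what is left of the response when a guide-resistant wild-type cDNA is present. In WT cells CYR61 went from 4.17 ± 0.673 to 56.9 ± 15.4 TPM (SD, n = 3) and KRT17 from 1.95 ± 0.728 to 38.2 ± 3.79 TPM. TRPM5, the cation channel of taste-type signalling, went from 399 ± 33.1 to 103 ± 52.6 TPM. The 10 largest rises, as log2 change ± SE, were MGP (a matrix protein, 4.84 ± 0.23), ERP27 (3.83 ± 0.29), KRT17 (3.76 ± 0.21), SOSTDC1 (a BMP antagonist, 3.53 ± 0.29), CYR61 (3.46 ± 0.25), ANKRD1 (3.12 ± 0.21), CXCL13 (a chemokine, 2.63 ± 0.22), TGFB2 (2.49 ± 0.32), IFITM3 (interferon-induced, 2.38 ± 0.17), AMOTL2 (2.29 ± 0.40), with adjusted p of at most 0.0062 (limma). The 10 largest falls were SULT1A3 (−4.72 ± 1.34), COL15A1 (a basement membrane collagen, −2.13 ± 0.36), TRPM5 (−2.11 ± 0.36), KIF26B (−2.08 ± 0.48), CNR1 (a cannabinoid receptor, −2.04 ± 0.15), ITGA4 (an integrin, −2.01 ± 0.27), EGFLAM (−1.93 ± 0.15), RGPD1 (−1.92 ± 0.31), DIRAS2 (−1.84 ± 0.19), PTPRD (a receptor phosphatase, −1.80 ± 0.45), with adjusted p of at most 0.048. SULT1A3 and RGPD1 have near-identical copies, so their values are uncertain.

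In WT cells camera called the YAP and TAZ list higher and the taste-type list lower, neither of which held with an estimated correlation. Among 24 YAP and TAZ targets, 8 rose and 1 fell (10 and 4 adjusted over the list alone, 13 and 6 in 16 libraries), with a median of 0.25 (0.53 in 16 libraries) (camera adjusted p = 9.49e-09, and 0.571 with an estimated correlation). ANKRD1 (3.12), CYR61 (3.46), TGFB2 (2.49) and IGFBP3 (1.77) had the smallest p. Of 14 taste-type signalling genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone, 0 and 11 in 16 libraries), with a median of −0.83 (camera adjusted p = 0.00106, and 0.687 with an estimated correlation). CALHM1 (−1.28), GNG13 (−1.43), TRPM5 (−2.11) and CALHM3 (−0.83) had the smallest p. Of 39 tuft markers, 2 rose and 8 fell (2 and 10 adjusted over the list alone, 5 and 16 in 16 libraries), with a median of −0.47 (−0.31 in 16 libraries) (camera adjusted p = 0.855). GNG13 (−1.43) and TRPM5 (−2.11) had the smallest p. Of 22 NF-kB and inflammatory genes, 2 rose and 0 fell (3 and 1 adjusted over the list alone, 6 and 2 in 16 libraries), with a median of 0.09 (camera adjusted p = 5.67e-05, and 0.527 with an estimated correlation). CXCL1 (1.47) and CXCL8 (1.21) had the smallest p. Of 79 cytosolic ribosomal protein genes, 4 rose and 0 fell (39 and 1 adjusted over the list alone, 35 and 0 in 16 libraries), with a median of 0.50 (camera adjusted p = 8.91e-40, and 0.295 with an estimated correlation). RPS15A (0.58) and RPL12 (0.49) had the smallest p. That last group held 32.76% of TPM in the skewed WT sgPOU2F3 replicate 1. In all, 877 of 13066 genes changed, 201 higher and 676 lower, with a median of −0.422 over all genes. After removal of the skewed libraries, 4721 were called (744 higher and 3977 lower, 875 shared). The split was 867 higher and 782 lower after median-ratio scaling and 1798 higher and 1546 lower after quantile normalization.

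The third comparison asked the same with the L191A cDNA. In L191A cells TNNT2, cardiac troponin T, went from 9.51 ± 1.94 to 149 ± 2.49 TPM (SD, n = 3), KRT8 from 377 ± 95.4 to 1587 ± 55 TPM and KRT18 from 310 ± 45.7 to 1233 ± 38 TPM. The 10 largest rises, as log2 change ± SE, were TNNT2 (3.85 ± 0.18), PHLDB2 (3.63 ± 0.25), PRSS23 (a serine protease, 3.61 ± 0.18), MYOF (myoferlin, 3.55 ± 0.41), IGFBP4 (3.51 ± 0.28), AMOTL2 (3.48 ± 0.40), ALPK2 (3.41 ± 0.31), TGFB2 (3.33 ± 0.32), THBS1 (3.33 ± 0.46), EDN1 (endothelin, 3.31 ± 0.26), with adjusted p of at most 0.00019 (limma). The 10 largest falls were MT1A (a metallothionein, −1.90 ± 0.37), NMU (a neuropeptide, −1.51 ± 0.17), TAS2R10 (−1.21 ± 0.19), ASCL2 (a tuft transcription factor, −1.20 ± 0.25), CLPSL2 (−1.13 ± 0.28), TFF3 (a trefoil factor, −1.09 ± 0.23), UBE2QL1 (−1.05 ± 0.28), CD8B (−1.02 ± 0.15), ASS1 (argininosuccinate synthase, −1.02 ± 0.28), FAM43B (−1.0 ± 0.27), with adjusted p of at most 0.0439. MT1A and TAS2R10 belong to families of similar sequence.

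Camera called the YAP and TAZ, mesenchymal and epithelial lists higher in L191A cells, none of which held with an estimated correlation. Of 24 YAP and TAZ targets, 16 rose and 0 fell (22 and 0 adjusted over the list alone, 19 and 0 in 16 libraries), with a median of 2.21 (camera adjusted p = 1.41e-21, and 0.375 with an estimated correlation). ANKRD1 (3.03), CYR61 (3.27), IGFBP3 (2.72) and CTGF (3.06) had the smallest p. Of 18 mesenchymal genes, 8 rose and 1 fell (13 and 1 adjusted over the list alone, 10 and 2 in 16 libraries), with a median of 0.78 (camera adjusted p = 0.00017, and 0.412 with an estimated correlation). TGFBI (1.70), TAGLN (2.30), SNAI2 (2.20) and VIM (1.86) had the smallest p. Of 26 epithelial genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone, 9 and 0 in 16 libraries), with a median of 0.70 (0.31 in 16 libraries) (camera adjusted p = 7.77e-05, and 0.48 with an estimated correlation). KRT18 (2.00), KRT8 (2.10), KRT19 (1.24) and CLDN4 (1.48) had the smallest p. Among 22 NF-kB and inflammatory genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone, 7 and 0 in 16 libraries), with a median of 0.41 (camera adjusted p = 0.0196, and 0.665 with an estimated correlation). ICAM1 (1.43) and CXCL8 (1.38) had the smallest p. Among 39 tuft markers, 0 rose and 4 fell (0 and 6 adjusted over the list alone, 0 and 20 in 16 libraries), with a median of −0.20 (−0.70 in 16 libraries) (camera adjusted p = 2.39e-09, and 0.48 with an estimated correlation). C11orf53 (−0.98), ASCL2 (−1.20), GNG13 (−0.94) and GFI1B (−1.0) had the smallest p. Among 14 taste-type signalling genes, 0 rose and 1 fell (1 and 2 adjusted over the list alone, 0 and 10 in 16 libraries), with a median of −0.35 (−0.97 in 16 libraries) (camera adjusted p = 9.83e-05, and 0.48 with an estimated correlation). GNG13 (−0.94) had the smallest p. In all, 783 of 13066 genes changed, 709 higher and 74 lower, with a median of 0.334 over all genes. Without the 2 skewed libraries, 1396 were called (961 higher and 435 lower, 757 shared). The split was 838 higher and 423 lower after median-ratio scaling and 860 higher and 623 lower after quantile normalization.

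How much of the empty-vector response stayed with each cDNA was read on the genes called there at 2-fold or more, in other libraries. The 445 genes that rose in empty-vector cells (median log2 change 1.69) had a median of 0.07 (0.16 in 16 libraries) in WT cells, where 73 rose and 6 fell (131 and 21 in the 16). In L191A cells their median was 1.30 (1.04), and 309 rose and 0 fell (326 and 3). The response of this set was larger in L191A than in WT cells by a median of 1.15 (0.81), with 231 genes called higher and 6 lower in that interaction (232 and 9). The 498 genes that fell (median −1.29) had a median of −0.71 in WT cells, where 146 fell and 1 rose, and of 0.04 in L191A cells, where 27 fell and 5 rose. In 16 libraries the medians were −0.56 and −0.25, and 284 fell and 5 rose in WT and 125 and 9 in L191A cells. At 0.05, fry, a set test of limma, called the difference between L191A and WT cells for the rising set and not for the falling set. The median of all genes moved in opposite directions in these lines. After the values were seen, the sets were also read less that median. The rising set then stood at 0.49 in WT and 0.97 in L191A cells (0.42 and 1.03 in 16 libraries), with 0.36 in the interaction (0.53). The falling set stood at −0.29 and −0.30 (−0.29 and −0.26). Between lines it was lower in L191A than in WT cells, by −0.81 under sgPOU2F3 and −0.79 under sgRosa. L191A cells thus started lower.

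**Figure D4:**
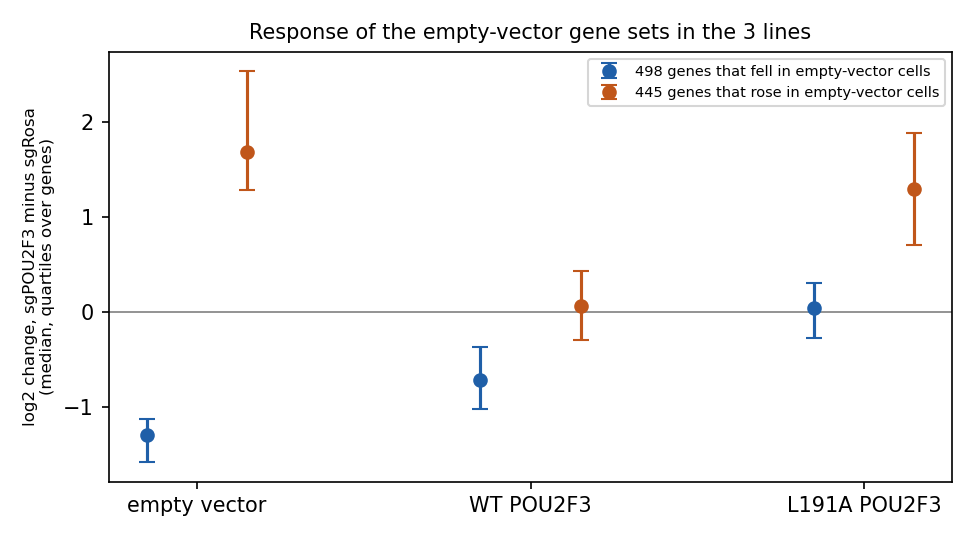
Log2 change, sgPOU2F3 minus sgRosa (y axis), of the 498 genes that fell and the 445 genes that rose in empty-vector cells, in the 3 lines, where points are medians and bars quartiles over genes. No allowance is made for the median of all genes. The falling set was already lower in L191A than in WT sgRosa cells.

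The difference of the response itself was then tested. Between WT and empty-vector cells camera called the inflammatory and YAP and TAZ lists lower, of which only the inflammatory list held with an estimated correlation. The 5 largest positive differences, as log2 ± SE, were TFF3 (3.02 ± 0.33), ANXA13 (2.58 ± 0.25), RTL9 (2.38 ± 0.48), TAS2R60 (2.32 ± 0.58), BIK (2.30 ± 0.27), and the 5 largest negative ones FOSL1 (−5.15 ± 0.45), ETS1 (a transcription factor, −4.74 ± 0.35), TGFBI (−4.53 ± 0.25), LIF (−4.51 ± 0.55), ITGA3 (an integrin, −4.48 ± 0.47), with adjusted p of at most 0.0242 (limma). Of 24 YAP and TAZ targets, 0 responded more and 17 less (0 and 17 adjusted over the list alone, 0 and 19 in 16 libraries). Their median was −2.15 (camera adjusted p = 9.57e-16, 0.243 with an estimated correlation, and fry p = 0.000148). Of 22 NF-kB and inflammatory genes, 0 responded more and 17 less (0 and 20 adjusted over the list alone, 0 and 19 in 16 libraries), with a median of −1.66 (camera adjusted p = 3.61e-18, and 0.0294 with an estimated correlation). Of 16 genes of MHC and antigen presentation, 0 responded more and 8 less (0 and 11 adjusted over the list alone, 0 and 11 in 16 libraries), with a median of −1.07 (camera adjusted p = 0.000133, and 0.0294 with an estimated correlation). Of 39 tuft markers, 7 responded more and 0 less (13 and 0 adjusted over the list alone, 22 and 0 in 16 libraries), with a median of 0.53 (camera adjusted p = 4.56e-09, and 0.6 with an estimated correlation). In all, 913 of 13066 genes differed, 224 higher and 689 lower, with a median of −0.264 over all genes. In 16 libraries, 3495 were called (1177 higher and 2318 lower, 913 shared). The split was 903 higher and 1091 lower after median-ratio scaling and 1525 and 1420 after quantile normalization.

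Between L191A and empty-vector cells, camera called the inflammatory and antigen presentation lists lower, and with an estimated correlation too. The 5 largest positive differences were PAX1 (3.95 ± 0.42), TAS2R60 (3.27 ± 0.58), TP53INP1 (a p53 target, 2.97 ± 0.44), CHAD (2.91 ± 0.35), RGPD2 (2.88 ± 0.68), and the 5 largest negative ones KRT17 (−4.50 ± 0.29), IL6 (−3.85 ± 0.26), CYR61 (−3.80 ± 0.35), FOSL1 (−3.58 ± 0.45), TGFBI (−3.30 ± 0.25), with adjusted p of at most 0.0235 (limma). RGPD2 has near-identical copies. CYR61 and KRT17 already stood at 35.4 ± 14 and 26.8 ± 6.3 TPM (SD, n = 3) in L191A sgRosa cells. Among 22 NF-kB and inflammatory genes, 0 responded more and 10 less (0 and 17 adjusted over the list alone, 0 and 20 in 16 libraries), with a median of −1.13 (camera adjusted p = 1.34e-29, and 0.00653 with an estimated correlation). Of 16 genes of MHC and antigen presentation, 0 responded more and 6 less (1 and 6 adjusted over the list alone, 1 and 9 in 16 libraries), with a median of −0.61 (camera adjusted p = 3.43e-10, and 0.00119 with an estimated correlation). Among 24 YAP and TAZ targets, 1 responded more and 7 less (2 and 10 adjusted over the list alone, 2 and 13 in 16 libraries), with a median of −0.71 (camera adjusted p = 6.52e-09, and 0.519 with an estimated correlation). In all, 795 of 13066 genes differed, 560 higher and 235 lower, with a median of 0.482 over all genes. After removal of the skewed libraries, 3039 were called (2054 higher and 985 lower, 795 shared). The split was 839 higher and 752 lower after median-ratio scaling and 990 higher and 986 lower after quantile normalization.

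Between L191A and WT cells, camera called the YAP and TAZ and epithelial lists higher, neither of which held with an estimated correlation. The 5 largest positive differences were CRIM1 (3.86 ± 0.81), ARHGAP23 (3.56 ± 0.73), MATN2 (a matrilin, 3.41 ± 0.37), TNNT2 (3.34 ± 0.26), SHROOM3 (3.29 ± 0.58), and the 5 largest negative ones TFF3 (−3.29 ± 0.33), ERP27 (−2.42 ± 0.41), MGP (−2.32 ± 0.32), APOBEC1 (an RNA editing enzyme, −2.06 ± 0.25), MT1A (−1.75 ± 0.52), with adjusted p of at most 0.0452 (limma). For the 24 YAP and TAZ targets, 12 responded more and 0 less (18 and 0 adjusted over the list alone, 13 and 0 in 16 libraries), with a median of 1.89 (0.97 in 16 libraries) (camera adjusted p = 0.00202, and 0.784 with an estimated correlation). Of 26 epithelial genes, 10 responded more and 0 less (16 and 0 adjusted over the list alone, 11 and 1 in 16 libraries), with a median of 1.25 (0.60 in 16 libraries) (camera adjusted p = 0.00369, and 0.776 with an estimated correlation). Of 79 cytosolic ribosomal protein genes, high in both skewed libraries, 0 responded more and 25 less (0 and 70 adjusted over the list alone, 0 and 3 in 16 libraries), with a median of −0.88 (−0.50 in 16 libraries) (camera adjusted p = 1.1e-76, and 0.186 with an estimated correlation). In all, 1531 of 13066 genes differed, 1404 higher and 127 lower, with a median of 0.794 over all genes. Without the 2 skewed libraries, 1722 were called (1494 higher and 228 lower, 1191 shared). The split was 925 higher and 782 lower after median-ratio scaling and 1189 higher and 1492 lower after quantile normalization.

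Under sgPOU2F3 the cDNAs were compared. L191A cells held less POU2F3 mRNA (646 against 1154 TPM, no overlap, limma adjusted p = 0.303). Its level was not separated from the L191A change. Camera called the tuft and taste-type lists lower in L191A than in WT cells and the YAP and TAZ list higher. None held with an estimated correlation. SCIN was at 3.66 ± 0.0115 TPM in L191A and 129 ± 22.5 TPM in WT cells (SD, n = 3). PLCB2 was at 22.2 ± 1.43 and 306 ± 121 TPM. The 10 genes highest in L191A relative to WT cells, as log2 difference ± SE, were TNNT2 (4.48 ± 0.18), MMP13 (a collagenase, 4.38 ± 0.26), IGFBP5 (4.17 ± 0.51), RBP2 (4.01 ± 0.30), MYOF (3.75 ± 0.41), IGFBP4 (3.72 ± 0.28), TNC (tenascin, 3.57 ± 0.29), EDN2 (3.55 ± 0.20), MMP1 (a collagenase, 3.50 ± 0.19), VTCN1 (3.45 ± 0.21), with adjusted p of at most 4.03e-05 (limma). The 10 lowest were SCIN (−4.79 ± 0.22), VWDE (−3.74 ± 0.25), PLCB2 (−3.64 ± 0.36), AGTR1 (an angiotensin receptor, −3.43 ± 0.20), PTGS2 (the inducible cyclooxygenase, −3.37 ± 0.27), ATP2A3 (a calcium pump, −3.33 ± 0.43), LIN28B (−3.24 ± 0.24), GNG13 (−3.22 ± 0.24), SPIB (an ETS factor of tuft cells, −3.09 ± 0.21), BIK (−2.90 ± 0.19), with adjusted p of at most 7.19e-05.

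By list under sgPOU2F3 the cDNAs differed as follows. Of the 39 tuft markers, 0 were higher and 20 lower (0 and 23 adjusted over the list alone, 1 and 34 in 16 libraries), with a median of −1.0 (camera adjusted p = 1.63e-20, and 0.275 with an estimated correlation). Of 14 taste-type signalling genes, 0 were higher and 11 lower (1 and 11 adjusted over the list alone, 1 and 13 in 16 libraries), with a median of −1.98 (camera adjusted p = 2.39e-15, and 0.149 with an estimated correlation). Of 8 genes of eicosanoid synthesis, 0 were higher and 5 lower (0 and 6 adjusted over the list alone, 0 and 6 in 16 libraries), with a median of −1.20 (camera adjusted p = 1.32e-07, and 0.0713 with an estimated correlation). Of the 24 YAP and TAZ targets, 16 were higher and 0 lower (19 and 0 adjusted over the list alone, 19 and 0 in 16 libraries), with a median of 1.83 (camera adjusted p = 2.57e-15, and 0.275 with an estimated correlation). Of 42 S phase genes, 20 were higher and 0 lower (27 and 0 adjusted over the list alone, 39 and 0 in 16 libraries), with a median of 0.57 (camera adjusted p = 7.85e-10, and 0.312 with an estimated correlation). Of 29 MYC and ribosome biogenesis genes, 18 were higher and 0 lower (22 and 0 adjusted over the list alone, 27 and 0 in 16 libraries), with a median of 0.87 (camera adjusted p = 3.2e-11, and 0.275 with an estimated correlation). In all, 1762 of 13066 genes differed, 1015 higher and 747 lower, with a median of 0.144 over all genes. With both skewed libraries left out, 4885 were called (2410 higher and 2475 lower, 1754 shared). The split was 1373 higher and 1519 lower after median-ratio scaling.

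Under the control guide, with the endogenous gene intact, camera again called the taste-type list lower in L191A than in WT cells, which did not hold with an estimated correlation. GNG13 was at 9.82 ± 3.47 against 137 ± 27.6 TPM (SD, n = 3) and PTGS2 at 1.58 ± 0.941 against 36.1 ± 11.6 TPM. POU2F3 mRNA itself was lower in L191A than in WT cells (−1.84, SE 0.48, limma adjusted p = 0.00647, and −0.94 without the skewed libraries). The 5 highest in L191A cells, as log2 difference ± SE, were ERP27 (4.32 ± 0.29), MGP (4.11 ± 0.23), KRT17 (3.25 ± 0.21), MMP13 (2.98 ± 0.26), MMP1 (2.96 ± 0.19), and the 5 lowest SCIN (−7.23 ± 0.22), VWDE (−4.98 ± 0.25), HIST1H4K (−4.93 ± 1.25), ATP2A3 (−4.80 ± 0.43), PLCB2 (−4.77 ± 0.36), with adjusted p of at most 0.00572 (limma). HIST1H4K is a near-copy of other histone genes and uncertain. Of 14 taste-type signalling genes, 0 were higher and 13 lower (0 and 13 adjusted over the list alone, 0 and 12 in 16 libraries), with a median of −2.09 (camera adjusted p = 4.49e-07, and 0.439 with an estimated correlation). Of the 39 tuft markers, 1 was higher and 28 lower (1 and 30 adjusted over the list alone, 3 and 28 in 16 libraries), with a median of −1.22 (camera adjusted p = 0.000126, and 0.835 with an estimated correlation). Of 42 S phase genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone, 41 and 0 in 16 libraries), with a median of 0.40 (0.69 in 16 libraries) (camera adjusted p = 1.79e-21, and 0.162 with an estimated correlation). Of 79 cytosolic ribosomal protein genes, high in the skewed L191A sgRosa library, 18 were higher and 0 lower (1 and 0 adjusted over the list alone, 4 and 1 in 16 libraries), with a median of 0.42 (0.17 in 16 libraries) (camera adjusted p = 2.06e-23, and 0.439 with an estimated correlation). The 498 genes that fell in empty-vector cells had a median of −1.46, with 442 lower and 3 higher (438 and 9 in 16 libraries), and of −0.79 less the median of all genes. In all, 7288 of 13066 genes differed, 1012 higher and 6276 lower, with a median of −0.668 over all genes. After removal of the skewed libraries, 7605 were called (1811 higher and 5794 lower, 6491 shared). The split was 3365 higher and 3174 lower after median-ratio scaling and 3255 higher and 2921 lower after quantile normalization.

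Against empty-vector cells under sgPOU2F3, camera called the inflammatory, YAP and TAZ and MYC lists lower and the taste-type list higher in WT cells, none of which held with an estimated correlation. The 5 highest in WT cells, as log2 difference ± SE, were PAX6 (a transcription factor of eye and endocrine cells, 5.18 ± 0.56), SCIN (4.81 ± 0.22), RGS21 (4.16 ± 0.29), DLG2 (4.05 ± 0.38), LIN28B (a regulator of let-7 microRNAs, 3.99 ± 0.24), and the 5 lowest FOSL1 (−4.58 ± 0.32), CLDN6 (a tight junction protein, −4.36 ± 0.18), PLAU (−4.23 ± 0.22), TGFBI (−4.14 ± 0.18), NUAK2 (−4.07 ± 0.28), with adjusted p of at most 8.08e-06 (limma). Of 22 NF-kB and inflammatory genes, 0 were higher and 21 lower (0 and 21 adjusted over the list alone, 0 and 21 in 16 libraries), with a median of −1.46 (camera adjusted p = 2.89e-16, and 0.0642 with an estimated correlation). Of the 24 YAP and TAZ targets, 0 were higher and 17 lower (0 and 17 adjusted over the list alone, 0 and 19 in 16 libraries), with a median of −1.62 (camera adjusted p = 6.56e-11, and 0.36 with an estimated correlation). Of 14 taste-type signalling genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone, 10 and 0 in 16 libraries), with a median of 1.17 (camera adjusted p = 2.48e-08, and 0.36 with an estimated correlation). Of 29 MYC and ribosome biogenesis genes, 0 were higher and 20 lower (0 and 26 adjusted over the list alone, 0 and 29 in 16 libraries), with a median of −1.13 (camera adjusted p = 6.85e-12, and 0.311 with an estimated correlation). In all, 2687 of 13066 genes differed, 871 higher and 1816 lower, with a median of −0.193 over all genes. Without the 2 skewed libraries, 5699 were called (2473 higher and 3226 lower, 2665 shared). The split was 1905 higher and 2079 lower after median-ratio scaling and 2410 higher and 2354 lower after quantile normalization.

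Against the same empty-vector cells, camera called the inflammatory list lower in L191A cells, and with an estimated correlation too. The 5 highest in L191A cells were NTS (neurotensin, 5.23 ± 0.19), PAX6 (5.22 ± 0.56), RBP2 (4.48 ± 0.30), PCOLCE (3.84 ± 0.21), PALMD (3.42 ± 0.25), and the 5 lowest GNG13 (−3.49 ± 0.24), PLA2G4A (a phospholipase, −3.36 ± 0.24), ATP2A3 (−3.31 ± 0.43), TUBB3 (a neuronal tubulin, −3.26 ± 0.27), IL6 (−3.08 ± 0.19), with adjusted p of at most 0.000154 (limma). Of 22 NF-kB and inflammatory genes, 0 were higher and 16 lower (0 and 20 adjusted over the list alone, 0 and 20 in 16 libraries), with a median of −1.14 (camera adjusted p = 9.4e-29, and 0.00736 with an estimated correlation). Of the 39 tuft markers, 3 were higher and 13 lower (3 and 16 adjusted over the list alone, 6 and 21 in 16 libraries), with a median of −0.58 (camera adjusted p = 3.61e-07, and 0.874 with an estimated correlation). Of the 24 YAP and TAZ targets, 1 was higher and 2 lower (3 and 2 adjusted over the list alone, 7 and 3 in 16 libraries), with a median of 0.08 (camera adjusted p = 0.334). In all, 495 of 13066 genes differed, of which 284 were lower and the rest higher, with a median of −0.06 over all genes. With both skewed libraries left out, 2991 were called (1081 higher and 1910 lower, 495 shared).

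Under sgRosa, camera called the S phase list lower and the MHC list higher in the WT than in the empty-vector line, of which only the MHC list held with an estimated correlation (but not in 16 libraries). The 5 highest in WT cells, as log2 difference ± SE, were PAX6 (4.90 ± 0.56), SCIN (4.79 ± 0.22), LIN28B (4.58 ± 0.24), RAB27B (4.01 ± 0.21), CLDN1 (a tight junction protein, 3.96 ± 0.25), and the 5 lowest CDH13 (a cadherin, −3.84 ± 0.32), TFF3 (−3.57 ± 0.23), EMP1 (−3.34 ± 0.22), TUBB3 (−3.31 ± 0.27), VIL1 (villin, −2.70 ± 0.32), with adjusted p of at most 4.73e-05 (limma). Of 42 S phase genes, 0 were higher and 16 lower (0 and 23 adjusted over the list alone, 0 and 39 in 16 libraries), with a median of −0.55 (camera adjusted p = 2.23e-21, and 0.215 with an estimated correlation). Of 16 genes of MHC and antigen presentation, 5 were higher and 0 lower (7 and 0 adjusted over the list alone, 10 and 0 in 16 libraries), with a median of 0.60 (camera adjusted p = 5.72e-05, and 0.0323 with an estimated correlation, but 0.0559 in 16 libraries). Among 14 taste-type signalling genes, 6 were higher and 1 lower (8 and 1 adjusted over the list alone, 11 and 2 in 16 libraries), with a median of 0.93 (camera adjusted p = 2.85e-05, and 0.966 with an estimated correlation). In all, 941 of 13066 genes differed, 597 higher and 344 lower, with a median of 0.077 over all genes. After removal of the skewed libraries, 4486 were called (2727 higher and 1759 lower, 941 shared). The split was 1189 higher and 1319 lower after quantile normalization.

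For the L191A line against the empty-vector line under sgRosa, camera called the tuft list lower and the YAP and TAZ and MHC lists higher, of which only the MHC list held with an estimated correlation. The 5 highest in L191A cells, as log2 difference ± SE, were NTS (5.16 ± 0.19), ERP27 (4.86 ± 0.29), PAX6 (4.72 ± 0.56), MGP (4.02 ± 0.23), PCOLCE (3.72 ± 0.21), and the 5 lowest HIST1H4K (−5.07 ± 1.25), GNG13 (−4.93 ± 0.24), PTGS2 (−4.79 ± 0.27), PLA2G4A (−4.59 ± 0.24), ATP2A3 (−4.17 ± 0.43), with adjusted p of at most 0.00947 (limma). PAX6 stood at 0.581 ± 0.161 TPM (SD, n = 3) in empty-vector sgRosa cells and at 46.1 ± 3.64 and 59.5 ± 43.9 TPM in WT and L191A sgRosa cells. Of the 39 tuft markers, 1 was higher and 28 lower (1 and 31 adjusted over the list alone, 5 and 26 in 16 libraries), with a median of −1.19 (−0.68 in 16 libraries) (camera adjusted p = 5.11e-07, and 0.612 with an estimated correlation). Of 24 YAP and TAZ targets, 10 were higher and 2 lower (12 and 2 adjusted over the list alone, 14 and 2 in 16 libraries), with a median of 0.56 (0.88 in 16 libraries) (camera adjusted p = 1.09e-11, and 0.461 with an estimated correlation). Of 16 genes of MHC and antigen presentation, 5 were higher and 0 lower (5 and 0 adjusted over the list alone, 9 and 0 in 16 libraries), with a median of 0.26 (camera adjusted p = 4.02e-07, and 0.00667 with an estimated correlation). In all, 4700 of 13066 genes differed, 646 higher and 4054 lower, with a median of −0.558 over all genes. Without the 2 skewed libraries, 5125 were called (1214 higher and 3911 lower, 4113 shared). The split was 2091 higher and 2015 lower after median-ratio scaling and 2040 higher and 1941 lower after quantile normalization.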

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

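The tests of explanations and of other splits below were all chosen after the results were seen, while the interactions themselves were planned. The response to sgPOU2F3 differed between lines by a test of the difference itself in each of the 3 interactions. It differed in 913 genes between WT and empty-vector cells, in 795 between L191A and empty-vector cells and in 1531 between L191A and WT cells. For the genes that rose in empty-vector cells the response was higher in L191A than in WT cells by a median of 1.15 (0.36 less the median of all genes).

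The line labels of the libraries were shuffled within each guide. Of 100 such splits, the real one included, 2, 3 and 4 gave as many genes for these 3 interactions. The highest other splits called 2475, 2384 and 5321 genes, well above the real counts of 913, 795 and 1531, which points to a structure of the samples. Every split above the real count kept the labels under 1 guide and exchanged 4 or 6 of the 6 under the other, so it called the constant difference between the lines. With each gene's constant difference removed, the real counts stayed the same and 1 split of 100, the real one, gave as many genes in each interaction (1, 1 and 0 genes in the highest other). That difference was computed from the real labels, so a split that exchanged all 6 labels under 1 guide was brought to about 0 by construction. This second count therefore could not exclude chance. Neither count could exclude a difference between the lines or the skewed libraries as a cause. For the 9 comparisons of 3 against 3 libraries, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts ran from 495 to 7288, and the highest other split called 1 gene for L191A against empty-vector cells under sgPOU2F3 and 0 for the others.

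After sgPOU2F3 in empty-vector cells YAP and TAZ targets had a median of 2.72, a camera call lost with an estimated correlation (adjusted p = 0.155). Length-trend removal gave 2.84 and median-ratio scaling 2.75, but all genes moved by only −0.13, too little for either to decide a cause. With the WT cDNA the response was lower (median −2.15), as loss of POU2F3 function would predict. That call was also lost with an estimated correlation. That this rise follows POU2F3 loss stays a hypothesis. Each line is a single stable line, so a difference between lines unrelated to POU2F3 stays open.

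The genes that fell in empty-vector cells were lower in L191A than in WT cells even under sgRosa, by −0.79 less the median of all genes. Without the skewed L191A sgRosa replicate 1 the value was −0.81, and with the length trend removed −0.76, which argues against both as the whole cause. A candidate explanation is that L191A protein competes with endogenous POU2F3, and each of the 3 L191A sgRosa libraries lay below WT, the highest at −0.70. POU2F3 mRNA was also lower in L191A than in WT sgRosa cells (−1.84, adjusted p = 0.00647, limma, and −0.94 without the skewed libraries). A difference between the stable lines would give the same values, so these cannot be told apart.

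The same genes were lower after sgPOU2F3 in WT cells by −0.29 less the median of all genes, despite the cDNA. Without the skewed WT sgPOU2F3 replicate 1 the value was −0.29, and with the length trend removed −0.30, which argues against both. POU2F3 mRNA fell in the WT line (1792 to 1154 TPM), so loss from a raised level stays open. So does a shortfall below empty-vector sgRosa cells. The ratio to their mean was 1.58. The lowest WT sgPOU2F3 library less the highest empty-vector sgPOU2F3 one was 0.86 of the highest empty-vector sgRosa library. Protein was not measured.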

How the results depend on the processing

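The removal of skewed libraries (with or without an estimated correlation), array weights, the length trend and response sets taken again within each setting (as read below) were chosen after seeing the data, and the other alternatives were planned. Counts of called genes moved by over 1.5 times under the following alternatives, and the cause was not tested. A line minus another stands for the difference of their sgPOU2F3 effects. A pseudocount of 0.1 gave 224 for sgPOU2F3 in WT cells and 701 for L191A minus WT. A pseudocount of 5 gave 2476 for sgPOU2F3 in WT cells and 3950 for L191A minus WT. No filter on low values gave 1491 for sgPOU2F3 in WT cells and 788 for L191A against empty vector under sgPOU2F3. A mean of at least 5 TPM, which tests fewer genes, gave 186 for sgPOU2F3 in WT cells, 475 for sgPOU2F3 in L191A cells, 269 for L191A against empty vector under sgPOU2F3, 551 for WT against empty vector under sgRosa, 589 for WT minus empty-vector, 461 for L191A minus empty-vector and 469 for L191A minus WT. Median-ratio scaling gave 3450 for sgPOU2F3 in empty-vector cells, 1649 for sgPOU2F3 in WT cells, 1261 for sgPOU2F3 in L191A cells, 1068 for L191A against empty vector under sgPOU2F3, 2892 for L191A against WT under sgPOU2F3, 1716 for WT against empty vector under sgRosa, 1994 for WT minus empty-vector and 1591 for L191A minus empty-vector. Quantile normalization gave 4187 for sgPOU2F3 in empty-vector cells, 3344 for sgPOU2F3 in WT cells, 1483 for sgPOU2F3 in L191A cells, 4764 for WT against empty vector under sgPOU2F3, 1328 for L191A against empty vector under sgPOU2F3, 3570 for L191A against WT under sgPOU2F3, 2508 for WT against empty vector under sgRosa, 2945 for WT minus empty-vector, 1976 for L191A minus empty-vector and 2681 for L191A minus WT. Removing both skewed libraries gave 6758 for sgPOU2F3 in empty-vector cells, 4721 for sgPOU2F3 in WT cells, 1396 for sgPOU2F3 in L191A cells, 5699 for WT against empty vector under sgPOU2F3, 2991 for L191A against empty vector under sgPOU2F3, 4885 for L191A against WT under sgPOU2F3, 4486 for WT against empty vector under sgRosa, 3495 for WT minus empty-vector and 3039 for L191A minus empty-vector. Removing L191A sgRosa replicate 1 alone, also from comparisons without its group, gave 5268 for sgPOU2F3 in empty-vector cells, 8206 for sgPOU2F3 in WT cells, 5906 for WT against empty vector under sgPOU2F3, 1537 for L191A against empty vector under sgPOU2F3, 4622 for L191A against WT under sgPOU2F3, 2904 for WT against empty vector under sgRosa, 3702 for WT minus empty-vector and 1674 for L191A minus empty-vector. Array weights gave 8953 for sgPOU2F3 in empty-vector cells, 8212 for sgPOU2F3 in WT cells, 2583 for sgPOU2F3 in L191A cells, 8372 for WT against empty vector under sgPOU2F3, 5813 for L191A against empty vector under sgPOU2F3, 7599 for L191A against WT under sgPOU2F3, 7647 for WT against empty vector under sgRosa, 6325 for WT minus empty-vector, 5375 for L191A minus empty-vector and 5867 for L191A minus WT. Removing the length trend gave 4141 for sgPOU2F3 in empty-vector cells, 2790 for sgPOU2F3 in WT cells, 1452 for sgPOU2F3 in L191A cells, 4767 for WT against empty vector under sgPOU2F3, 1344 for L191A against empty vector under sgPOU2F3, 3513 for L191A against WT under sgPOU2F3, 2361 for WT against empty vector under sgRosa, 2667 for WT minus empty-vector and 1952 for L191A minus empty-vector. Fitting only the groups compared, which leaves fewer libraries for the spread, gave 4883 for sgPOU2F3 in empty-vector cells, 221 for sgPOU2F3 in WT cells, 144 for sgPOU2F3 in L191A cells, 2378 for L191A against empty vector under sgPOU2F3, 3678 for WT against empty vector under sgRosa, 184 for L191A against empty vector under sgRosa, 1681 for L191A against WT under sgRosa, 2374 for WT minus empty-vector, 319 for L191A minus empty-vector and 300 for L191A minus WT.

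Replicate number as a block gave 1440 for sgPOU2F3 in WT cells and 4029 for L191A minus WT. No other contrast's total moved by over 1.5 times. The numbers were not taken as pairs: 15 of 45 correlations between same-numbered libraries exceeded 0.1 (range −0.577 to 0.594), and 5 of 18 libraries correlated best with their own number.

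The genes that fell in empty-vector cells, read in WT cells, had a median of −0.71, which became −0.37 with median-ratio scaling and −0.40 without the length trend, and −0.80 (without WT sgPOU2F3 replicate 3) to −0.56 (without WT sgPOU2F3 replicate 1) with 1 of 12 libraries left out. The genes that rose in empty-vector cells, read in WT cells, had a median of 0.07, which became 0.30 with median-ratio scaling, 0.32 with quantile normalization, 0.34 without the length trend and 0.32 with the set defined at 4-fold, and 0.03 (without WT sgPOU2F3 replicate 3) to 0.16 (without WT sgPOU2F3 replicate 1) with 1 of 12 libraries left out. The genes that fell in empty-vector cells, read in L191A cells, had a median of 0.04, which became −0.07 with a pseudocount of 5, 0.01 with a mean TPM of at least 5, −0.28 with median-ratio scaling, −0.35 with quantile normalization, −0.25 without both skewed libraries, −0.24 without L191A sgRosa replicate 1, −0.24 with array weights, −0.33 without the length trend, 0.11 fitting only the groups compared and −0.17 with the set defined at 4-fold, and −0.25 (without L191A sgRosa replicate 1) to 0.25 (without L191A sgRosa replicate 2) with 1 of 12 libraries left out. The genes that rose in empty-vector cells, read in L191A cells, had a median of 1.30, which became 1.56 with a pseudocount of 0.1, 1.08 with a pseudocount of 5, 1.20 with no filter on low values, 1.39 with a mean TPM of at least 5, 0.84 with median-ratio scaling, 0.79 with quantile normalization, 1.03 without both skewed libraries, 1.03 without L191A sgRosa replicate 1, 1.10 with array weights, 0.82 without the length trend, 0.68 with the set defined at 1.5-fold and 1.88 with the set defined at 4-fold, and 1.04 (without L191A sgRosa replicate 1) to 1.41 (without L191A sgRosa replicate 3) with 1 of 12 libraries left out.

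With each library of the groups compared, and no other, left out in turn, counts ran from 1283 (without empty-vector sgRosa replicate 3) to 1810 (without empty-vector sgPOU2F3 replicate 2) for sgPOU2F3 in empty-vector cells, from 1728 (without empty-vector sgPOU2F3 replicate 2) to 2696 (without WT sgPOU2F3 replicate 3) for WT against empty vector under sgPOU2F3, from 352 (without L191A sgPOU2F3 replicate 3) to 375 (without empty-vector sgPOU2F3 replicate 1) for L191A against empty vector under sgPOU2F3, from 537 (without WT sgRosa replicate 1) to 1226 (without WT sgPOU2F3 replicate 3) for WT minus empty-vector, from 292 (without empty-vector sgRosa replicate 3) to 2519 (without L191A sgRosa replicate 2) for L191A minus empty-vector, from 417 (without empty-vector sgRosa replicate 2) to 751 (without empty-vector sgRosa replicate 3) for WT against empty vector under sgRosa, from 1421 (without empty-vector sgRosa replicate 3) to 7493 (without L191A sgRosa replicate 3) for L191A against empty vector under sgRosa, from 478 (without L191A sgPOU2F3 replicate 1) to 1766 (without L191A sgRosa replicate 3) for sgPOU2F3 in L191A cells, from 995 (without L191A sgPOU2F3 replicate 1) to 1644 (without WT sgPOU2F3 replicate 1) for L191A against WT under sgPOU2F3, from 418 (without WT sgRosa replicate 1) to 7260 (without L191A sgRosa replicate 2) for L191A minus WT, from 4450 (without WT sgRosa replicate 1) to 8916 (without L191A sgRosa replicate 3) for L191A against WT under sgRosa, from 110 (without WT sgRosa replicate 1) to 2860 (without WT sgPOU2F3 replicate 3) for sgPOU2F3 in WT cells. List medians after sgPOU2F3 ran from −0.95 (without empty-vector sgPOU2F3 replicate 2) to −0.68 (without empty-vector sgRosa replicate 3) for tuft markers in empty-vector cells, from 2.63 (without empty-vector sgPOU2F3 replicate 2) to 2.78 (without empty-vector sgPOU2F3 replicate 1) for YAP and TAZ targets in empty-vector cells, from −0.70 (without L191A sgRosa replicate 1) to −0.04 (without L191A sgRosa replicate 2) for tuft markers in L191A cells, from 1.70 (without L191A sgRosa replicate 1) to 2.57 (without L191A sgRosa replicate 3) for YAP and TAZ targets in L191A cells, from −0.53 (without WT sgPOU2F3 replicate 2) to −0.31 (without WT sgPOU2F3 replicate 1) for tuft markers in WT cells, from 0.05 (without WT sgPOU2F3 replicate 3) to 0.53 (without WT sgPOU2F3 replicate 1) for YAP and TAZ targets in WT cells. With an estimated correlation the calls of tuft markers in empty-vector cells (median −0.80), YAP and TAZ targets in empty-vector cells (median 2.72), YAP and TAZ targets in WT cells (median 0.25), tuft markers in L191A cells (median −0.20) and YAP and TAZ targets in L191A cells (median 2.21) were lost.

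Turns of sign are given where a gene or list was called with all libraries or under the alternative. For lists the direction is that of camera. After median-ratio scaling the sign turned for PRIM1 (0.21), CENPA (0.15), SHMT2 (0.09), CEBPG (0.13) and HIST1H2BD (0.01) (L191A against empty vector under sgRosa), MVD (0.05) and HIST1H2BD (0.07) (L191A against WT under sgRosa) and HLA-C (−0.07) (L191A minus WT). After quantile normalization the sign turned for SPARC (0.07), FOXJ1 (0.23), SFTPB (0.28), SP5 (0.10), HIST2H2BE (0.14) and HIST1H2BD (0.01) (L191A against WT under sgRosa). Without both skewed libraries the sign turned for POU2F3 (−0.53) (sgPOU2F3 in L191A cells) and POU2F3 (0.37) (L191A against empty vector under sgRosa). Without L191A sgRosa replicate 1 the sign turned for POU2F3 (−0.53) (sgPOU2F3 in L191A cells). With array weights the sign turned for POU2F3 (−0.57) (sgPOU2F3 in L191A cells), ABCA3 (0.37) (WT against empty vector under sgPOU2F3) and POU2F3 (0.49) (L191A against empty vector under sgRosa). Without the length trend the sign turned for TRAF1 (0.11) and CEBPG (0.25) (L191A against empty vector under sgRosa), POU2F1 (0.27) and SFTPB (0.03) (L191A against WT under sgRosa) and TRAF1 (−0.12) (L191A minus WT). With 1 library left out, direction turned for cytosolic ribosomal proteins in WT against empty vector under sgRosa without WT sgRosa replicate 1 (0.13) and POU2F3 in sgPOU2F3 in L191A cells without L191A sgRosa replicate 1 (−0.53). POU2F3 in L191A against empty vector under sgRosa, called on neither side, also turned without L191A sgRosa replicate 1 (0.37). POU2F3 itself reached 0.91 in L191A cells without L191A sgRosa replicate 2. Of 1525 gene results, 595 kept their direction and side of the threshold under every alternative run, 506 lost a call in at least 1 and 19 turned sign in at least 1 with a call on 1 side or both. No read depth was recorded, so its limits could not be set.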

Other observations

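The bitter taste receptor family was looked at after its members appeared among the largest falls, so it was chosen after its values were seen. Counts by limma without the 2 skewed libraries are in brackets. Of 16 TAS2R genes tested, 10 [14] fell in empty-vector cells after sgPOU2F3 (median log2 change −1.21), 2 [7] in WT cells (−0.70) and 1 [7] in L191A cells (−0.15), and none rose. Under sgPOU2F3, 11 [14] were higher in WT than in empty-vector cells and 10 [12] lower in L191A than in WT cells. Under sgRosa these were 7 [11] and 15 [14]. L191A against empty-vector cells gave 2 [6] higher and 0 [1] lower under sgPOU2F3, and 2 [2] and 6 [6] under sgRosa.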
